A study of Mus musculus with 6 samples.

How the data were processed

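Messenger RNA libraries from 6 samples of DC2.4 cells, a mouse dendritic cell line, were analysed: 3 from cells transfected with the empty pTT5 vector and 3 from cells labelled as overexpressing Vdbp. Per the labels, the cells were passaged 48 h after transfection and then placed under selection, and total RNA was extracted with TRIzol. HISAT2 and StringTie are named in the submitters' processing notes without a version. The counting tool, the genome build and the annotation release are not given in the sources used here. The deposited count table holds unnormalised counts per Ensembl gene, and the authors also deposited an FPKM table for the same genes and libraries. The deposited FPKM values were a rescaling of the counts: each equalled the count divided by the gene length of the table and by 1 constant per library. The constant was read from genes with over 50 counts, and the largest relative gap among all genes with counts was 5.1e-15. The counts were therefore used for every result, and the FPKM table for alternatives. Of the gene identifiers, 99.9% were found in GENCODE M21, which is on GRCm38, and 98.3% of these had the same start and end there. Gene positions and gene lengths are those of the deposited table, and GC contents for the correction described below came from GENCODE M21.

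Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, a minimum total count of 15 and a minimum proportion of 0.7, libraries were scaled by TMM, and a quasi-likelihood F test with group as the only term compared the libraries labelled Vdbp with the empty-vector libraries. P-values were two-sided and adjusted by the Benjamini-Hochberg method over 12844 tested genes, with a threshold of 0.05. Levels are CPM, counts scaled to the TMM-adjusted library size, with the SD over 3 libraries, and log2 fold changes carry the model's SE and 95% confidence interval. A count of 0 was read as allowing up to 3 counts, and this floor covers counting error only. Library totals lay between 15563800 and 16710975 counts. The labels do not say whether the 3 libraries of a group came from separate transfections or from 1 culture, so the p-values measure only the spread between these samples.

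Before the data were examined, 35 lists of genes of known function and 15 lists of cell type markers were fixed, together with the comparisons, the alternatives and the rule for naming genes. Lists with at least 5 tested members (37 of 50) were tested with camera from limma 3.58.1, which compares the members with all other tested genes, at a preset inter-gene correlation of 0.01 and with adjustment over all lists together. The test was repeated with the correlation estimated for each list, and with fry, which asks whether a list's genes move one way without comparing them with other genes. The naming rule took Gc, then genes past the adjusted threshold by size of change and by p, then members of the described lists that passed, and, for a described list with no member past the threshold, the member with the highest mean CPM. The genes taken by size or p had to reach 5 CPM in the higher group, be protein-coding, carry a symbol that is not a clone-based or predicted name, and show no overlap between the groups. No gene met the threshold, so the rule named Gc and 1 gene for each of 17 described lists. All other genes named were chosen after their values were seen.

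Alternatives were RLE, upper-quartile and total-count scaling, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of 1 CPM in all libraries of a group, the replicate number as a block, limma on log2 FPKM with pseudocounts of 1 and 0.1 (with and without a filter at 0.5 FPKM), an adjusted p under 0.01, a 2-fold minimum, glmTreat against 1.2-fold, and leaving out each library in turn. A pair of alternatives was chosen after seeing the data. The first removed from each library a smooth trend on gene length and GC content, fitted with mgcv 1.9.3 and passed to edgeR as an offset. The other left out the libraries at the ends of the first principal component, empty-vector replicate 2 and Vdbp replicate 1. All 10 ways of splitting the 6 libraries into 3 and 3 were also fitted. Sequence windows of the Gc transcripts were searched in all other transcripts with Biostrings 2.70.1.

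The procedure was tested on simulated data, 3 sets of about the depth and spread of these libraries, in which some genes were changed by a known amount. Without a trend between libraries, edgeR recovered 54.2% of genes changed 1.5-fold, 82.6% of those changed 2-fold and 99.0% of those changed 4-fold, and 7.83% of its calls were false. DESeq2 had 10.6% false calls in the same sets and the unfiltered edgeR fit 12.5%. With a GC and length trend between libraries added, edgeR recovered 52.2% of the 1.5-fold changes and the fit with the offset 74.1%. Of their calls 3.11% and 7.10% were false. The sets with the trend also took the spread of each gene from the fit with the offset, not from the uncorrected fit. Recovery with and without the trend can therefore not be compared. A list shifted by a known amount passed camera at the preset correlation in 3 of 3 sets and with an estimated correlation in 0 of 3, while 0 of 60 random lists passed either test. Of the fixed lists, which were not shifted, 0 to 2 passed at the preset correlation in a set with the trend, with or without the offset, and 0 in sets without it. Genes were simulated independently of each other apart from that trend, so these sets do not show how either test behaves with correlated members. The RT-qPCR measurements mentioned in the labels and the raw reads were not used here.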

Results

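The data were RNA sequencing counts from DC2.4, a mouse dendritic cell line, and the comparison set cells labelled as overexpressing Vdbp against cells that carried the empty vector, with 3 libraries in each group. The design text of the series states that the overexpression of Vdbp in dendritic cells was examined. Vdbp is the vitamin D-binding protein, a carrier of vitamin D metabolites in blood, and its mouse gene carries the symbol Gc. The empty-vector libraries held 16376659, 16621938 and 16710975 counts for replicates 1, 2 and 3, and the libraries labelled Vdbp held 16506563, 16529104 and 15563800. Of 54532 genes in the table, 24135 had counts in at least 1 library and 12844 were tested, and the tested genes held 99.9% of all counts.

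No transcript of the gene named on the labels was detected in either group. Gc (ENSMUSG00000035540, chromosome 5, 89417522 to 89457898, minus strand) had 0 counts in all 3 empty-vector libraries and 0 counts in all 3 libraries labelled Vdbp. At these depths a count of 0 allows a level of up to 0.180 to 0.193 CPM per library (3 counts). The levels of Vdbp that the labels say were measured by RT-qPCR were not analysed here. Because the counts hold no reads of Gc, the groups are named by their labels, and each direction given is that of the libraries labelled Vdbp relative to the empty-vector libraries.

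The libraries did not part fully by group along the main axis of variation, before or after a correction for gene length and GC content. The first principal component of log2 CPM held 41.2% of the variance and put empty-vector replicates 1 and 2 and Vdbp replicate 3 on its negative side (−7.98, −26.7 and −6.62), and empty-vector replicate 3 and Vdbp replicates 1 and 2 on its positive side (4.91, 30.5 and 5.94). After the correction the first component held 32.1% of the variance. All 3 libraries labelled Vdbp then lay on its positive side (14.7, 12.1 and 1.65) and empty-vector replicates 1 and 2 on its negative side (−14.5 and −22.1), while empty-vector replicate 3 (8.22) lay above Vdbp replicate 3. Pairs of libraries correlated across genes, which are not independent replicates, at 0.979 to 0.993, and the closest pair across the groups (0.993) was as close as the closest pair within a group (0.992). Libraries also differed in a trend with the GC content of genes. Spearman's rho across genes between a library's deviation from the mean and GC content was −0.07, −0.62 and 0.07 in empty-vector replicates 1, 2 and 3, and 0.73, −0.03 and −0.40 in Vdbp replicates 1, 2 and 3. The log2 fold change between the groups followed GC content with a rho of 0.51 and gene length with a rho of −0.21 across genes, and these became 0.03 and −0.01 after the correction for both. Its rho with coding length, across tested protein-coding genes, was −0.143 before this correction and −0.133 after it, so that trend remained. The mitochondrial share of counts was 1.83%, 2.61% and 1.82% in empty-vector replicates 1, 2 and 3 and 1.49%, 1.80% and 2.18% in Vdbp replicates 1, 2 and 3.

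**Figure D1:**
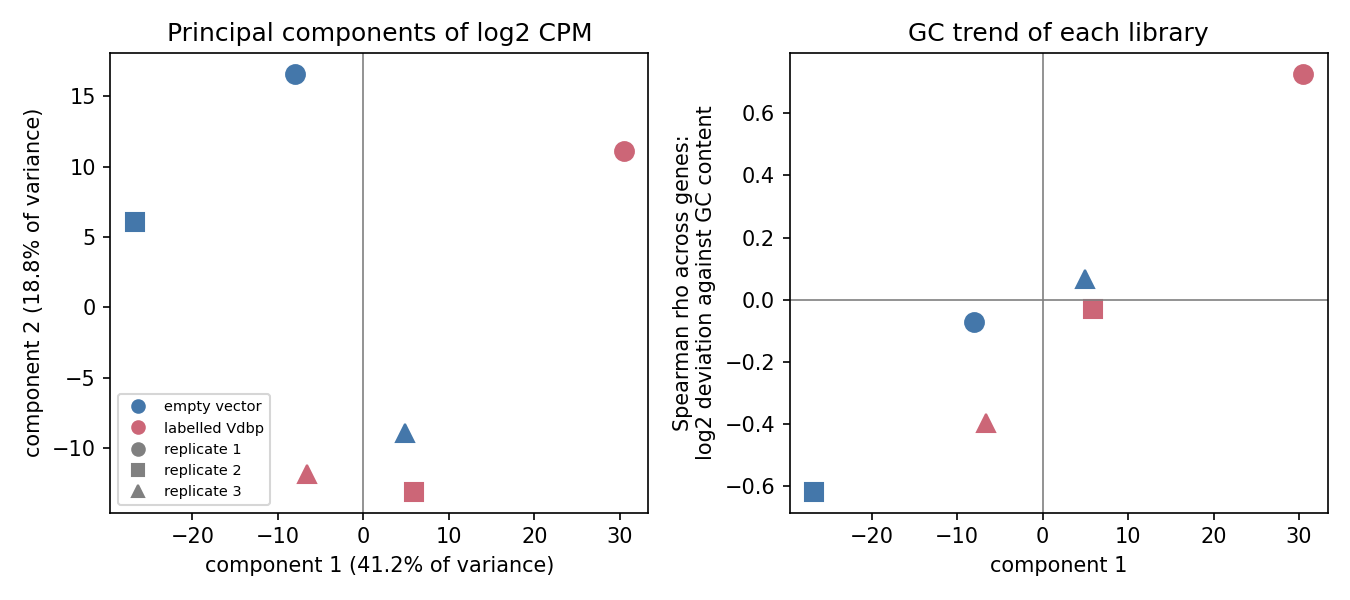
Left, the first and second principal components of log2 CPM for the 6 libraries (each point is 1 library, colour gives the group and shape the replicate). Right, the first component against Spearman's rho across genes between each library's log2 deviation and GC content. Vdbp replicate 1 (rho 0.73) and empty-vector replicate 2 (rho −0.62) lie at the ends of the first component.

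Cd274, Arg1 and Wfdc17 were among the genes with the smallest p-values and had less RNA in the libraries labelled Vdbp. Cd274, which encodes PD-L1, an inhibitory ligand for T cells (ENSMUSG00000016496, chromosome 19, 29367455 to 29388095), averaged 100.1 ± 6.80 CPM with empty vector and 66.0 ± 6.33 CPM with the Vdbp label (SD, n = 3 each), a log2 fold change of −0.60 (95% interval −0.83 to −0.37). Arg1, the arginine-degrading enzyme arginase 1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484), averaged 19.08 ± 1.63 and 11.03 ± 0.40 CPM, a log2 fold change of −0.79 (−1.07 to −0.51). Wfdc17, a small secreted protein of macrophages and other myeloid cells (ENSMUSG00000069792, chromosome 11, 83703991 to 83706268), averaged 41.4 ± 12.2 and 22.7 ± 1.00 CPM, a log2 fold change of −0.87 (−1.28 to −0.46). In all 3 genes every library labelled Vdbp lay below every empty-vector library.

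These differences did not pass the test that was planned. edgeR called 0 of 12844 genes at an adjusted p under 0.05; the smallest adjusted p, shared by Arg1 and Cd274, was 0.601, and that of Wfdc17 was 0.781. At an unadjusted p under 0.05 there were 687 genes (361 higher and 326 lower), against 642 by chance. That count was 1146 with the length and GC offset, and it ranged from 258 without empty-vector replicate 2 to 1158 without empty-vector replicate 3 and 1532 without Vdbp replicate 3. limma-voom also called 0 genes, with 701 at an unadjusted p under 0.05. DESeq2 called 4 genes, with 626 at an unadjusted p under 0.05: Cd274, Arg1 and Wfdc17 were lower, with adjusted p of 0.00965, 0.0177 and 0.0248, and Entpd4b was higher, with an adjusted p of 0.0248. Entpd4b had 9, 7 and 19 counts with empty vector and 21, 111 and 54 with the Vdbp label, and its level is uncertain because it is a close copy of Entpd4. With the length and GC offset, edgeR called 2 genes, Cd274 (log2 fold change −0.53, adjusted p 0.0111) and Arg1 (−0.76, adjusted p 0.0449), both lower. In that fit Cd274 still passed without empty-vector replicate 2 or 3 or Vdbp replicate 3 but not without empty-vector replicate 1 (adjusted p 0.208) or Vdbp replicate 1 (0.0890) or 2 (0.160), and Arg1 passed only without empty-vector replicate 3 (0.00325). Without empty-vector replicate 3 the uncorrected fit called 22 genes (4 higher and 18 lower), Arg1 and Wfdc17 among them. Without empty-vector replicate 2 it called 1, which was neither Cd274 nor Arg1.

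**Figure D2:**
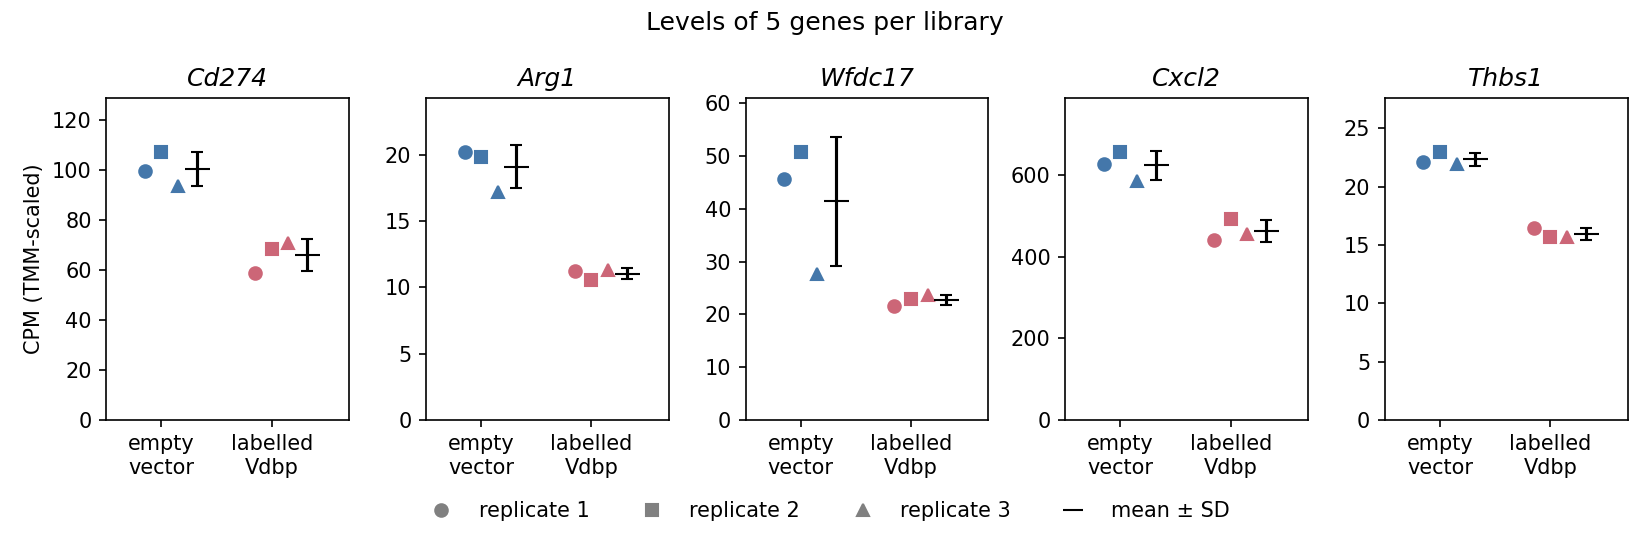
TMM-scaled CPM of 5 genes in each library (points, shape gives the replicate) with the mean and SD of each group of 3 libraries (bars). In each gene all 3 libraries labelled Vdbp lie below all 3 empty-vector libraries, and none of the 5 passed the edgeR threshold (smallest adjusted p 0.601).

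The size of the changes that remained possible was limited for most genes. The 95% interval of the fold change lay within 2-fold for 11470 tested genes (89.3%) and within 1.5-fold for 9077 (70.7%). The median absolute log2 fold change was 0.13 and the median SE 0.14. The 3 and 3 libraries did not overlap for 1396 genes (10.9%), where chance gives 10%.

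The 12 protein-coding genes with the smallest p in each direction, among those without overlap between the groups and with at least 5 CPM in the higher group, are given next. Entpd4b, at 0.70 and 3.80 CPM, lay under that level. Cxcl2, a neutrophil-attracting chemokine, averaged 624 ± 36.3 CPM with empty vector and 463 ± 26.1 CPM with the Vdbp label (log2 fold change −0.43, SE 0.09). Thbs1, the matrix glycoprotein thrombospondin 1, averaged 22.4 ± 0.57 and 15.9 ± 0.49 CPM (−0.49, SE 0.11), and Fos, an immediate early transcription factor, 33.7 ± 5.14 and 21.1 ± 4.23 CPM (−0.68, SE 0.16). Pfkfb3, a regulator of glycolytic flux, had a log2 fold change of −0.36 (SE 0.09), and Lyst, a protein of lysosomal trafficking, of −0.42 (SE 0.11). The other lower genes were Cacna1d (−0.69), Slamf7 (−0.64), Mmp8 (−0.65) and H2-M2 (−0.48). The 12 higher genes included S100a4, a calcium-binding protein (6.74 ± 1.90 and 10.7 ± 1.98 CPM, log2 fold change 0.67, SE 0.21), Pik3r6, a regulatory subunit of a phosphoinositide 3-kinase (0.59), Dusp2, a phosphatase of MAP kinases (0.43), the splicing proteins Sf3b5 (0.42) and Snrpd2 (0.45), and Gadd45gip1, a protein of the mitochondrial ribosome (0.51). Pgp (0.44), Atg4d (0.43), Tspan4 (0.37) and Imp3 (0.36) followed, and Rpl7a (0.53) and Eno1b (0.49) are uncertain because similar copies of each exist in the genome. None of the 24 passed over all tested genes in the main edgeR fit (adjusted p of 0.601 to 0.781). In the split that put Vdbp replicate 3 with empty-vector replicates 1 and 2, edgeR without a filter on low counts called 599 genes. With the labelled groups the unfiltered fit called 89 genes. Of those named above they included Arg1, Cacna1d, Cd274, Cxcl2, Fos, Mmp8, Slamf7 and Wfdc17, which were lower, and Eno1b, Entpd4b, Gadd45gip1, Rpl7a, S100a4, Sf3b5 and Snrpd2, which were higher. The length and GC correction lowered the log2 fold change of Dusp2 to 0.27 and of Tspan4 to 0.22. All were chosen after their values were seen. The sign of none of them changed in any alternative fit, but the choice by small p without overlap made such a change unlikely in advance.

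Lists of genes that act in dendritic cell function were next compared, 9 of which were described whatever their result and did not pass camera. No member of any of the lists passed the main edgeR fit over all genes, while DESeq2 called the members Cd274 and Arg1. For vitamin D handling, 10 of 14 members were tested, with a median log2 fold change of −0.01 (adjusted p 0.8001). Vdr, the vitamin D receptor, was at 1.87 ± 0.36 CPM with empty vector and 1.83 ± 0.60 CPM with the Vdbp label, and Lgmn, the protease legumain and the member with the highest level, at 809 ± 22.02 and 745 ± 38.4 CPM. For class I antigen presentation all 20 members were tested, with a median of 0.07 (adjusted p 0.189, and 0.735 with an estimated correlation). B2m, the light chain of class I molecules, averaged 2336 ± 344 and 2093 ± 147 CPM. Without Vdbp replicate 3 the class I list passed (median 0.13, adjusted p 0.0477). After the length and GC correction its direction turned to lower (median −0.02, adjusted p 0.968). The class II list had 9 of 15 members tested and a median of 0.15 (adjusted p 0.189), which the correction lowered to 0.04 (adjusted p 0.561). The class II chain genes H2-Aa, H2-Ab1 and H2-Eb1 and the regulator Ciita were not among those tested. Their group means were at most 0.179 CPM, so the result does not cover the class II molecules themselves. The level of this list was 0.29 log2 units in Vdbp replicate 1 against −0.01 and 0.02 in Vdbp replicates 2 and 3. Its member Ctss, a protease that cleaves the invariant chain, averaged 596 ± 39.0 and 502 ± 41.3 CPM, and the invariant chain itself, Cd74, 168 ± 4.72 and 203 ± 20.3 CPM. With the correction the log2 fold change of Cd74 went from 0.27 to 0.14 and that of B2m from −0.16 to −0.03.

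The list of co-stimulation and dendritic cell maturation genes had 14 of 23 members tested, a median and a mean log2 fold change of 0.01, and a camera direction that was lower (adjusted p 0.631). Adjusted over the list alone, 1 member was lower, Cd274 (adjusted p 0.00131), and none was higher. The co-stimulatory genes Cd86 (83.3 ± 9.02 and 78.0 ± 12.6 CPM) and Cd40 (58.5 ± 5.00 and 60.8 ± 6.94 CPM) differed by less than the SD within a group, and Marcksl1 had the highest level (220 ± 2.07 and 237 ± 19.7 CPM). Of the inhibitory and tolerogenic factors, 13 of 22 were tested, with a median of −0.01 (adjusted p 0.446). Adjusted over the list alone, 1 of them was lower, Arg1 (adjusted p 0.000615), and Lgals3, the lectin galectin 3 with the highest level, averaged 1289 ± 98.7 and 1285 ± 191 CPM. Inflammatory cytokines had a median of −0.03 over 16 tested members (adjusted p 0.362), with Csf1 at 347 ± 15.4 and 346 ± 27.5 CPM and Tnf at 234 ± 19.0 and 230.4 ± 26.1 CPM. Chemokines had a median of −0.06 over 20 tested members (adjusted p 0.134). Adjusted over the list alone, 2 chemokines were lower, Cxcl2 (adjusted p 0.0125) and Ccl6 (13.4 ± 1.48 and 9.47 ± 0.51 CPM, adjusted p 0.0380), and Ccl3, at 1859 ± 239 and 1643 ± 174 CPM, had the highest level. The medians of interferon-stimulated genes (44 tested) and of complement genes (13 tested) were −0.02 and 0.04 (adjusted p 0.727 and 0.368), and their members with the highest level were Irf9 (977 ± 36.9 and 990.4 ± 37.8 CPM) and C3 (840.3 ± 33.7 and 807 ± 90.3 CPM). In the 9 lists, no member was higher when adjusted over the list alone. After the length and GC correction the members lower when adjusted over the list alone were 1 of the co-stimulation list, 2 of the inhibitory factors, 2 chemokines and 1 of the class II list, and none was higher.

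Of the 37 lists tested, 8 passed camera with the preset correlation, 6 higher and 2 lower, and none of the 8 passed with an estimated correlation or with fry. Nuclear-encoded genes of oxidative phosphorylation had a median log2 fold change of 0.15 (34 of 43 members higher; adjusted p 2.67e-05, and 0.571 with an estimated correlation). Examples were the ATP synthase subunit Atp5o (82.8 ± 20.9 and 107.8 ± 11.02 CPM), the complex III subunit Uqcrc1 (369 ± 7.06 and 435 ± 55.0 CPM) and the complex I subunit Ndufb8 (52.6 ± 14.2 and 70.7 ± 14.4 CPM), while Atp5b had the highest level (1984 ± 46.8 and 2059 ± 191 CPM). Cytosolic ribosomal proteins had a median of 0.14 (35 of 52 higher; adjusted p 2.67e-05, and 0.571 with an estimated correlation), with Rps16 at 405 ± 79.0 and 526 ± 73.5 CPM, Rplp1 at 1157 ± 166 and 1443 ± 149 CPM and Rplp0, the most abundant, at 3167 ± 225 and 3335 ± 517 CPM. ATF4 and amino acid response genes had a median of 0.16 (19 of 23 higher; adjusted p 0.00158, and 0.571 with an estimated correlation). Among them were the amino acid transporter Slc7a5 (219 ± 7.15 and 262 ± 33.7 CPM), Pck2 (112 ± 10.7 and 136 ± 23.1 CPM) and Phgdh, the first enzyme of serine synthesis and the most abundant (869.8 ± 41.3 and 1036 ± 145 CPM).

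Glycolysis genes had a median log2 fold change of 0.13 (18 of 20 members higher; adjusted p 0.00158, and 0.571 with an estimated correlation), with Pfkl at 103 ± 16.03 and 139 ± 26.3 CPM, Tpi1 at 1072 ± 75.1 and 1275 ± 128 CPM and Pkm, the most abundant, at 4528 ± 479 and 5333 ± 766 CPM. Adjusted over the list alone, its member Pfkfb3 was lower (111 ± 8.63 and 86.6 ± 1.93 CPM, adjusted p 0.0438), against the direction of the list; after the length and GC correction 1 member was lower and 1 higher. The counted level of Gapdh in this list rested on 1 library: it was 231 CPM in Vdbp replicate 2 and 21.4 to 28.5 CPM in the other libraries. Reads shared with similar copies elsewhere in the genome were not searched for in Gapdh or in other list members. Cholesterol synthesis and uptake genes had a median of 0.10 (18 of 23 higher; adjusted p 0.00762, and 0.452 with an estimated correlation), with Mvd at 60.7 ± 9.88 and 77.5 ± 15.4 CPM, Lss at 47.8 ± 0.87 and 56.3 ± 6.75 CPM, and Srebf2, the transcription factor of the pathway, at 295 ± 26.6 and 342 ± 49.0 CPM. Actin cytoskeleton genes had a median of 0.08 (18 of 27 higher; adjusted p 0.0383, and 0.571 with an estimated correlation), with Actb at 2156 ± 108 and 2533 ± 293 CPM, Coro1a at 353 ± 30.9 and 430.4 ± 68.2 CPM, Pfn1 at 870.3 ± 118 and 1073 ± 189 CPM and Actg1 at 992 ± 39.5 and 1150.0 ± 96.4 CPM. The length and GC correction lowered the median of the ATF4 list to 0.06, of oxidative phosphorylation to 0.09, of ribosomal proteins to 0.09, of glycolysis to 0.08 and of the actin list to 0.04, where it no longer passed (adjusted p 0.166), while the median of the cholesterol list was then 0.12. Several of the examples shrank by over 1.5 times with the correction. The log2 fold change went from 0.29 to 0.14 in Coro1a, 0.30 to 0.14 in Pfn1, 0.25 to 0.11 in Phgdh, 0.25 to 0.13 in Slc7a5 and 0.24 to 0.11 in Pkm. It went from 0.21 to 0.09 in Srebf2, 0.35 to 0.19 in Mvd, 0.32 to 0.18 in Rplp1, 0.05 to 0.02 in Atp5b and 0.07 to −0.0009 in Rplp0. Without Vdbp replicate 1 the ATF4, glycolysis and actin lists no longer passed and their medians fell to 0.07, 0.06 and 0.02. Calls were also lost where the median stayed similar or was larger: the actin list without empty-vector replicate 2 (0.09) and 3 (0.11), and the cholesterol list without empty-vector replicate 3 (0.09) and Vdbp replicate 3 (0.14).

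The 2 lists that passed in the lower direction held matrix and sensing genes. Extracellular matrix and adhesion genes had a median log2 fold change of −0.09 and a mean of −0.17 (18 of 24 members lower; adjusted p 0.00115, and 0.452 with an estimated correlation). Adjusted over the list alone, 4 of its members were lower and none was higher: Thbs1 (adjusted p 0.0234), the collagenase Mmp8 (12.6 ± 1.55 and 8.04 ± 1.46 CPM, adjusted p 0.0234), the laminin chain Lama5 (2.53 ± 0.48 and 1.22 ± 0.27 CPM, adjusted p 0.0234) and the macrophage elastase Mmp12 (93.2 ± 13.8 and 67.0 ± 11.4 CPM, adjusted p 0.0346). After the length and GC correction the list had a median of −0.15, and 9 members were lower when adjusted over the list alone. Spp1, the secreted phosphoprotein osteopontin, was the most abundant member at 11302 ± 1275 and 9261 ± 1436 CPM. Pattern recognition receptors and their adaptors had a median of −0.15 (22 of 27 lower; adjusted p 0.00158, and 0.571 with an estimated correlation), and none passed when adjusted over the list alone. After the correction its median was −0.10. The C-type lectin receptor genes Clec4n (7.09 ± 0.86 and 4.83 ± 0.26 CPM) and Clec4e (194 ± 18.7 and 151 ± 23.3 CPM), the Toll-like receptor gene Tlr6 (21.3 ± 1.77 and 17.4 ± 1.60 CPM) and the endotoxin co-receptor Cd14 (675 ± 46.5 and 651 ± 33.6 CPM) were among its members. The examples of the 8 lists, other than the most abundant member of each, were chosen after their values were seen.

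In 6 of the 8 lists the levels of single libraries overlapped between the groups. Vdbp replicate 1, with the strongest positive trend on GC content (rho 0.73), had the highest level of all 6 libraries in each of the 6 higher lists, and empty-vector replicate 2, with the strongest negative trend (rho −0.62), the lowest. These libraries also had the lowest (1.49%) and the highest (2.61%) mitochondrial share. For oxidative phosphorylation, the median deviation of the members from their mean was −0.07, −0.12 and 0.01 log2 units in empty-vector replicates 1, 2 and 3, and 0.19, 0.10 and −0.06 in Vdbp replicates 1, 2 and 3. In the cholesterol list the levels of the 3 libraries labelled Vdbp (0.07, 0.05 and 0.04) all lay above those of the empty-vector libraries (−0.01, −0.09 and −0.05). In the ATF4 list they also did, but replicate 3 of both groups was at −0.02.

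**Figure D3:**
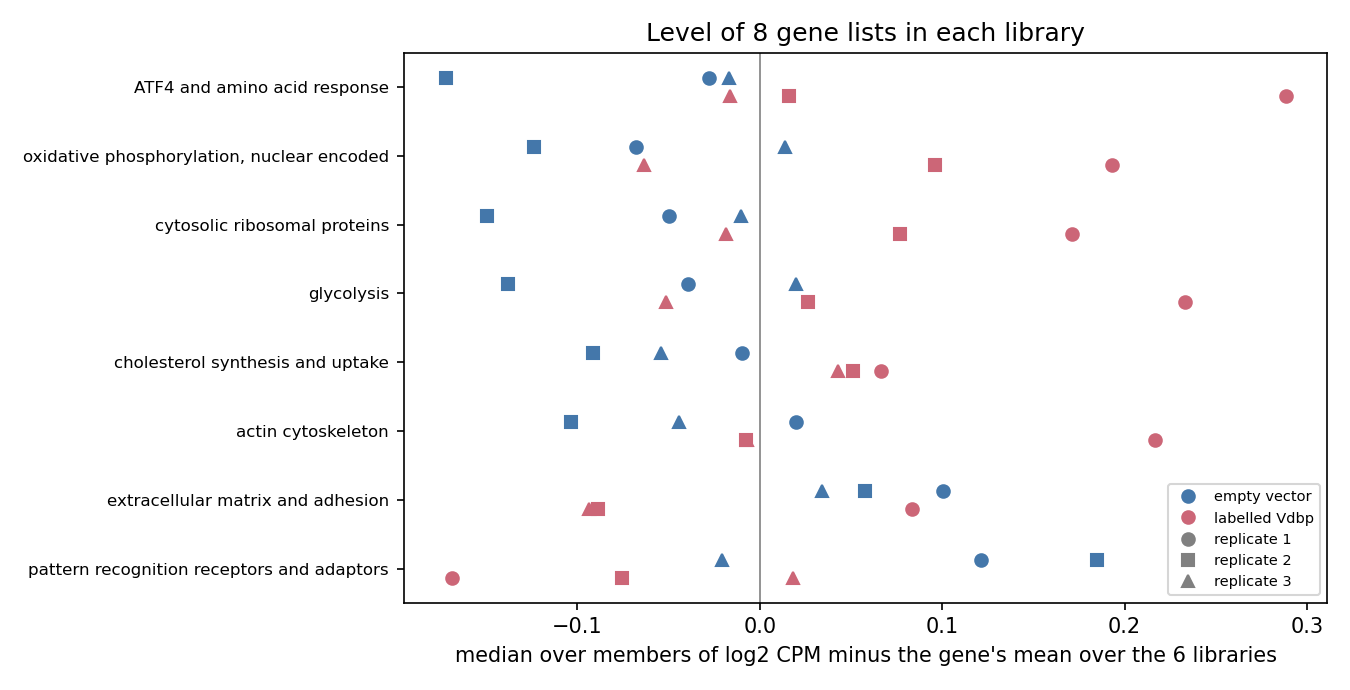
Level of the 8 lists in each library, as the median over members of log2 CPM minus the gene's mean over the 6 libraries (points, colour gives the group and shape the replicate). Vdbp replicate 1 is highest and empty-vector replicate 2 lowest in the 6 higher lists, and the groups overlap in all lists but those of cholesterol synthesis and uptake and of the ATF4 response, where replicate 3 of both groups is at −0.02.

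Over all 6 libraries and without a correction, 29 tested lists did not pass camera, with median log2 fold changes from −0.13 to 0.15 and a lowest adjusted p of 0.134, and 9 of them had a higher and 20 a lower direction. In the list of cytosolic nucleic acid sensing the median was −0.04 and the mean 0.01, and the direction of the test was higher (adjusted p 0.818). Among the immediate early genes (median −0.09 over 16 tested members, adjusted p 0.134), 1 member was lower when adjusted over the list alone, Fos (adjusted p 0.0232). This list passed in the lower direction after the length and GC correction (median −0.14, adjusted p 5.77e-05, and 0.184 with an estimated correlation), without empty-vector replicate 2 (adjusted p 8.20e-05) and without Vdbp replicate 1 (0.00482). After the correction, NF-kB targets (median −0.07, adjusted p 0.00977) and macrophage and monocyte markers (median −0.06, adjusted p 0.0484) also passed in the lower direction, and genes of S phase and DNA replication in the higher one (median 0.06, adjusted p 0.00800). With an estimated correlation the adjusted p of these 3 lists was 0.415, 0.415 and 0.396. Another 13 lists, all of cell type markers, had fewer than 5 tested members and were not tested.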

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

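The length and GC offset and the fit without the libraries at the ends of the first component were tests chosen only after the results were seen. The count of 0 genes by edgeR stayed at 0 with RLE, upper-quartile and total-count scaling, limma-voom, the filter of 1 CPM, limma on filtered FPKM with either pseudocount, an adjusted p under 0.01, the 2-fold minimum and glmTreat. It became 4 with DESeq2, 89 without a filter on low counts (18 of the 68 named genes among them), 4 with limma on unfiltered log2(FPKM + 1), 2 with the length and GC offset and 2 without the libraries at the ends of the first component. The cause was not tested. Without these end libraries no named gene was called, so neither Cd274 nor Arg1 passed there. The 4 genes of the unfiltered FPKM fit were predicted genes and not those of DESeq2. Leaving out 1 library gave 0 to 22 genes, with 22 without empty-vector replicate 3 and 1, not a named gene, without empty-vector replicate 2. The labels do not say that a replicate number marks a shared day or batch. Correlations of the deviations of like-numbered libraries were 0.14, 0.03 and −0.27. These were taken without removing the GC trend and cannot exclude a shared batch. With the replicate number as a block edgeR called 0 genes and 8 lists passed.

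The 8 lists past camera were the same 8 with RLE scaling, without a filter and with the block. The offset gave 11, with 7 of the 8 kept and 4 added, and leaving out 1 library gave 6 to 9, with 5 of the 8 kept without Vdbp replicate 1. The fit without the libraries at the ends of the first component gave 6, of which 2, the matrix and cholesterol lists, were among the 8. The medians of the other 6 shrank in it: actin from 0.08 to 0.01, glycolysis from 0.13 to 0.01, ATF4 from 0.16 to 0.03, ribosomal proteins from 0.14 to 0.04, oxidative phosphorylation from 0.15 to 0.05 and pattern recognition from −0.15 to −0.08. The count was 0 with an estimated correlation (smallest adjusted p 0.452), 0 with fry (0.0591) and 0 with the offset and an estimated correlation together (0.178). The cause was not tested. In simulated data, whose genes were drawn independently, the estimated correlation also passed 0 of 3 lists with a known shift. Not passing it is therefore no sign that a list lacked a shift. Those data cannot decide the matter for correlated lists, and the estimated correlation of the 8 ran from −0.03 (cholesterol) to 0.49 (glycolysis). The cholesterol value lay below the preset 0.01, so for that list the lost call cannot come from a higher correlation. Of the genes chosen after their values were seen for their p, a call or their list, 46 in all, none changed sign in 870 fits of alternatives and 71 estimates moved by more than 1 SE. The way these genes were chosen made a change of sign unlikely in advance, so its absence is no evidence of a group difference. Of 5 genes named for their function after their values were seen, 4 changed sign in some alternative (Vdr, Cd86, Cd40 and Tnf), as did 8 of the 17 most abundant list members, none past the threshold. Gc had no reads, so its level gave no test value in any alternative. Its counts of 0 do not exclude a level of up to 0.193 CPM in a library.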

Other observations

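Of the tests below, those of depth and of the insert for Gc, the splits for the count of genes by edgeR and for the lists after the correction, all 3 tests of the split that exchanged a library of each group and the length and GC correction itself were chosen only after the results were seen. Apart from any difference between the groups, several genes of the macrophage and monocyte list were abundant. Of its 15 members, 13 reached 1 CPM in every library. Means over the 6 libraries were 1773 CPM for the lysozyme gene Lyz2, 1224 CPM for Cd68, 627 CPM for Adgre1, 597 CPM for Csf1r and 237 CPM for Trem2. Other members were low, such as Apoe (7.09 CPM), Mrc1 (4.40 CPM) and Ly6c2 (1.40 CPM). Mertk (0.112 CPM) and Cd163 (0.0104 CPM) did not reach 1 CPM in every library. The pan dendritic cell list had 3 of 9 members at that level: Itgax averaged 50.3 CPM and Zbtb46 2.77 CPM, while Flt3 (0.222 CPM) and Batf3 (0.0402 CPM) had at most 6 and 3 counts in a library. Of the markers of type 1 conventional dendritic cells 5 of 10 reached 1 CPM, with Wdfy4 at 207 CPM, Irf8 at 56.7 CPM and Xcr1 at 0.213 CPM, and of type 2 markers 3 of 10, with Sirpa at 601 CPM and Irf4 at 0.284 CPM. Of the T cell list Cd28 averaged 48.9 CPM, Cd5 40.1 CPM and Il7r 27.7 CPM, and of the endothelial list Vwf 43.7 CPM. No member of the NK cell, mast cell, fibroblast, epithelial or erythroid list reached 1 CPM in every library. Genes with a large share of the counts included Fth1, which encodes the ferritin heavy chain, at 17423 ± 680 CPM with empty vector and 16381 ± 1341 CPM with the Vdbp label. Gpnmb averaged 7480 ± 239 and 6794 ± 809 CPM, and the protease gene Ctsk 4676 ± 29.1 and 4098 ± 225 CPM. They were picked after their values were seen, and mt-Co1, Eef1a1, Pkm and Eef2 also had large shares. Afp, a relative of Gc in the albumin gene family and on the same chromosome, averaged 82.5 ± 4.17 and 90.4 ± 4.08 CPM (log2 fold change 0.13, edgeR adjusted p 0.781).

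The gene named on the labels had 0 counts in every library. Too little depth is argued against, since it would hide only levels under the floor of 3 counts, at most 0.193 CPM, and not those of an overexpressed transcript. Reads lost to a similar gene are also argued against: 0 of 1746 windows of 100 bases from the Gc transcripts occurred in a transcript of another gene. An insert whose sequence does not match mouse Gc, such as a coding sequence from another species or one altered in its codons, may leave no counts, and it cannot be told apart from an absence of the transcript, because the table held 0 genes other than mouse Ensembl genes and Gc itself had 0 counts. Whether the libraries labelled Vdbp differed from the others in Vdbp therefore stays open in these data.

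For the 8 lists past camera, the tables argue against the trend with GC content and gene length between libraries as the whole cause, since 7 of the 8 passed in the same direction at the preset correlation after its removal. With an estimated correlation none of the 8 passed, before its removal (smallest adjusted p 0.452) or after it (0.178). That test also passed 0 of 3 simulated lists with a known shift. With the trend removed, 6 medians shrank by over 1.5 times (ATF4 0.16 to 0.06, oxidative phosphorylation 0.15 to 0.09, ribosomal proteins 0.14 to 0.09, glycolysis 0.13 to 0.08, pattern recognition −0.15 to −0.10, and actin, which no longer passed, 0.08 to 0.04). Short coding sequences could matter because the oxidative phosphorylation and ribosomal lists hold short genes. The medians of 6 of the 8 lists lay outside the central 95% of random lists matched for coding length and GC content. Those of the actin (84.6th percentile) and glycolysis (96.5th percentile) lists lay inside. Random members were drawn independently, while real members can be correlated (estimated at 0.27 in the ATF4 list). That range may thus be too narrow, so the test cannot exclude this cause. The matched lists had medians of 0.03 for oxidative phosphorylation and 0.05 for ribosomal proteins, below the observed 0.15 and 0.14. The correction for gene length and GC content hardly changed the trend of the log2 fold change with coding length (rho −0.143 before and −0.133 after). The weight of a single library stays open, since without Vdbp replicate 1 only 5 of the 8 were kept. With 10 splits of the 6 libraries a share under 0.1 cannot be had; the labelled split gave 8 lists and the highest of the others also 8, so that 3 of 10 splits gave at least as many, and after the correction the labelled split gave 11 and the highest other 5 (1 of 10). An effect of the treatment named on the labels stays open and untested, given the lack of Gc counts.

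Another split of the libraries gave far more genes than the labelled one, which points to a structure of the samples. With replicate 3 exchanged between the groups (empty-vector replicates 1 and 2 with Vdbp replicate 3, against empty-vector replicate 3 with Vdbp replicates 1 and 2), edgeR called 113 genes, 102 of them higher on the side of empty-vector replicate 3, whereas the labelled split and each of the other 8 called 0. The trend with GC content and gene length is argued against as its cause, since 226 genes were called after the correction and 89 were called in both fits. Short coding sequences had the values they need. The median coding length was 549 bases in the 89 called protein-coding genes that had one, against a lower quartile of 864 among tested genes. It was 741 bases in genes called after the correction. A difference between libraries in how short transcripts were recovered could give this and was not tested. Exchanged labels of these 2 libraries, with 113 genes in that split, cannot be told apart from such a structure, because every other split also exchanges 1 library per group and Gc, which could have shown it, had no counts. No biological explanation was tested, as the labels name nothing that parts the libraries in this way.

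Values of other splits follow for the remaining counts, with 10 splits and no share under 0.1 to be had. For genes called by edgeR the labelled split gave 0 and the highest other 113. All 10 of 10 splits gave at least as many, which a count of 0 fixes in advance, so this share decides nothing. Without a filter on low counts the labelled split gave 89 and the highest other 599. For DESeq2 the labelled split gave 4 and the highest other 348, and 3 of 10 gave at least as many. All 4 genes kept at least 50% of their log2 fold change after the GC and length correction. Without any single library 0 of the 4 lost over 50%. These genes were called in the same 6 libraries and had no overlap between the groups. That made such a loss unlikely in advance, so its absence is no evidence of a group difference. For edgeR after the correction the labelled split gave 2 and the highest other 226, and 2 of 10 gave at least as many. Cd274 and Arg1 kept at least 93.0% of the corrected log2 fold change without any single library. Their choice by a call in these libraries made that likely too. Even so, their adjusted p then ranged from 0.00173 to 0.208 and from 0.00325 to 0.407, and the corrected fit called 148 genes without empty-vector replicate 3.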
